A study of Homo sapiens with 2191 samples.

How the data were processed

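Cell-free DNA from blood serum was studied in 1221 patients with hepatocellular carcinoma (HCC, the main primary cancer of the liver) and 970 healthy controls, 1 library per sample. Per the labels' protocols, the DNA was bisulfite-converted, which turns unmethylated cytosine into a base read as T and leaves methylated cytosine read as C, and the target regions were captured with padlock probes, single-stranded probes that close into a circle over their target. Libraries were sequenced as read pairs. Per the submitters' processing notes, reads were handled with Trim Galore, cutadapt 1.4.1 and Bowtie2, and positions are on build hg19. The caller, the alignment settings and any removal of duplicate reads are not given in the sources used here.

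The deposited table held 467 CpG sites on 22 chromosomes, none of them on X or Y, with 3 measures for each site and sample. These were the deposited beta value, a fraction from 0 to 1, and the deposited counts of reads with T and of reads with C. Every row of the table matched 1 sample by its name. The deposited beta value equalled the count of C reads over all reads within 0.0005. Where a site had no read, the deposited beta value was 0. This applied to 144302 values, 14.1% of all, 12.0% of those of patients and 16.7% of those of controls. For this reason the methylation level was computed from the counts, in percent, and used only where a sample had at least 20 reads at the site. That minimum left out 22.1% of the values of patients and 36.8% of those of controls.

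The groups were taken from the labels, which gave no other property of the samples. They gave no batch, date or centre, so each library was assumed to come from a separate person, and p-values measure the spread between these libraries. No pair of libraries had the same T and C counts at more than 50% of the sites they shared. The highest share in any pair was 5.97%. Total reads over the 467 sites ran from 13347 to 521984 in patients (median 54002, quartiles 31940 and 104116) and from 12890 to 160451 in controls (median 23514, quartiles 18112.5 and 35125.5). The median number of reads per site was 64 in patients and 31 in controls. The exact (Clopper-Pearson) 95% interval of a level runs from 27.2% to 72.8% for 10 methylated of 20 reads. It runs from 30.2% to 66.9% for 15 of 31 reads and from 37.2% to 62.8% for 32 of 64 reads. Such intervals cover counting error only and treat reads as independent molecules. How copies made by PCR were handled is not given in the sources used here, so reads may not be independent.

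Each site was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the level per sample, HCC minus healthy, two-sided, with Benjamini-Hochberg adjustment over the 467 sites. A site counted as changed at an adjusted p under 0.05 and a difference of means of at least 5 percentage points. The test was made on levels per sample because the sample is the replicate. A quasi-binomial logistic model on the counts was run as an alternative. The spread was compared with limma on the absolute deviation from the group median. A site counted as more variable at an adjusted p under 0.05 and an SD at least 1.5 times as large. The area under the ROC curve (AUC) of a site is the chance that a patient drawn at random has a higher level than a control, with ties counted as equal. Its 95% interval came from 2000 bootstrap draws. All sites together were used in an L1-penalised logistic regression (C = 0.1, 10-fold cross-validation, medians of the training folds for missing values) in scikit-learn 1.9.0 with Python 3.11.15. Correlations were tested with 100000 permutations.

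The sites named in the text were the 10 changed sites with the largest positive and the 10 with the largest negative difference, at most 1 per 1000 bases. The thresholds, the named-site rule, the coverage minimum and the alternatives called planned below were chosen before the data were examined. On levels simulated for the comparison of HCC with healthy at all 467 sites, limma called 0 of 347 unchanged sites as changed, with 5 of them under the adjusted p. It called all 60 sites changed by 8 points, and none of 60 changed by 3 points, 58 of which passed the adjusted p. In this simulation each site was drawn on its own, at the real depth, with the spread of controls in both groups. A wider spread in patients, movement shared between sites and an effect of preparation on the level were not simulated. With permuted group labels the classifier had an AUC of 0.498. In the results, a number of sites is given as a percentage of the 467 sites unless another total is named.

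The higher sites named had a level in this many patients and controls: 916 and 310 at chr6:41528449, 979 and 240 at chr17:80358809, 1124 and 806 at chr2:113931518, 1090 and 841 at chr6:31527889, and 1133 and 783 at chr19:36233435. There were 888 and 332 at chr17:55456535, 1133 and 756 at chr16:29757318, 1221 and 968 at chr21:36421467, 1135 and 646 at chr10:101606024, and 963 and 221 at chr5:171538557. Of the lower sites, chr10:88684020 had 988 and 919, chr4:38673144 had 928 and 338, chr1:158259914 had 539 and 287, chr13:112612344 had 451 and 202, and chr6:170494251 had 1077 and 330. The site chr13:112602462 had 567 and 128, chr10:126827002 had 833 and 370, chr7:27155000 had 814 and 507, chr13:106834942 had 893 and 392, and chr3:194826585 had 1019 and 326. The deepest of them was chr21:36421467, with a median of 489 reads in patients and 171 in controls. Over the 467 sites the median number of samples with a level was 1001 patients and 645 controls, and the lowest 357 and 48.

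Libraries were also grouped by which sites had no read at all, without use of methylation, after the data had been seen. Sites whose absence correlated above 0.7 were joined, and 2 sets of at least 10 sites on at least 3 chromosomes were found. Set A held 16 sites on 8 chromosomes and set B held 11 sites on 5 chromosomes. A set was called absent from a library when more than 50% of its sites had no read. By this rule the libraries fell into 3 profiles, called library profiles here and treated as technical batches. Of all libraries, 151 lay near the dividing line for set A, with 30% to 70% of its sites without a read, and 92 near that for set B. Values within profiles needed at least 20 samples of each group at a site.

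Alternatives covered the scale and kind of test, the coverage minimum, the size threshold, filters on missing values, the number in the sample titles as a block, read depth, library profiles, the deposited beta values and the classifier. As covariates, 5 principal components of the share of reads per site were used, which held 47.5% of its variance. For the comparison matched on total reads, equal numbers of both groups were drawn within steps of 0.2 in log2 total reads, which gave 581 libraries of each group with medians of 31587 reads in patients and 30859 in controls. A panel of diagnostic sites, a panel of prognostic sites, gene lists and the position of sites relative to genes had also been planned. They were not analysed here, because no annotation of build hg19 was given and the table names sites by position only. The gene table at hand is of another build, so sites are given by position without a gene.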

Results

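Methylation of serum cell-free DNA, the short DNA fragments that dying cells release into blood, was compared between 1221 patients with hepatocellular carcinoma (HCC) and 970 healthy controls at 467 CpG sites. The series title names diagnosis and prognosis of HCC as the purpose. No outcome of the patients was in the labels, so the comparison of patients with controls was the 1 comparison made. Libraries of patients were deeper, with a median of 54002 reads over all sites against 23514 in controls. A level was used at a median of 83.1% of the sites per patient and 60.6% per control.

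Changed sites with little methylation in healthy serum were higher in patients, and most changed sites with high methylation were lower. Of the 467 sites, 92 were higher and 73 lower in HCC, together 35.3% (limma, adjusted p under 0.05 and at least 5 percentage points). The median difference was 9.35 points over the higher sites and -7.59 points over the lower sites. A difference of at least 10 points was reached by 40 higher and 14 lower sites. Without a size threshold, 370 sites passed the adjusted p, with 34.7% of all sites higher and 44.5% lower, so 43.9% of the sites passed with a difference under 5 points. Libraries differed in whether 2 sets of sites, called A and B, had any reads. Within libraries in which both sets were read, 72 sites were higher and 65 lower. Within libraries without reads at set A, 76 were higher and 61 lower, of the 71.5% of sites that could be tested. With principal components of the share of reads per site as covariates 82 sites were changed. Among libraries of both groups matched on total reads 58 were higher and 41 lower, and over the sites changed in all libraries the median difference was 0.662 times as large (quartiles 0.596 and 0.740).

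**Figure D1:**
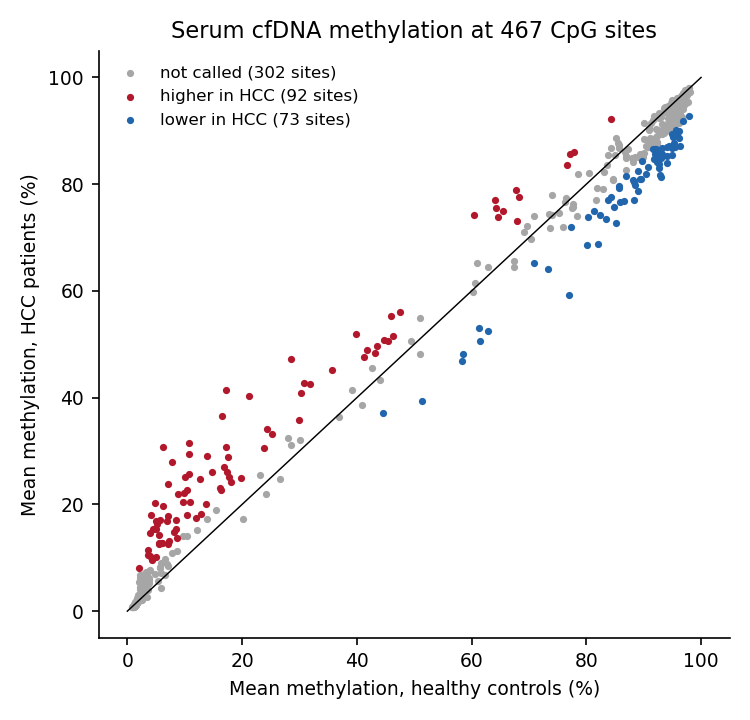
Mean methylation level of each of the 467 CpG sites in healthy controls (x axis, percent) and HCC patients (y axis, percent). Each point is 1 site, the line marks equal means, and the 92 higher and 73 lower sites lie above and below it.

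Among changed sites, the direction followed the level in controls. Of the sites with a healthy mean under 10%, 25.5% of all, 36 were higher, 0 lower and 83 not changed. Without the size threshold, 79 of these sites passed the adjusted p as higher and 12 as lower. For the lowest of these sites a fall of 5 points was out of reach. Among the 40 sites from 10% to 30%, 30 were higher and 0 lower, with a median difference of 7.51 points. Of the 46 sites from 30% to 70%, 22 were higher and 7 lower. Of the 75 sites from 70% to 90%, 4 were higher and 28 lower. Among the sites at 90% or more, 40% of all, most were not changed, 38 were lower and 0 higher, and the median difference was -2.46 points. A rise of 5 points was out of reach for the highest of these, and 7 passed the adjusted p as higher. The classes by healthy level were chosen after the data had been seen. The changed sites lay in 120 regions, with sites no more than 200 bases apart joined. Of the 81 regions with at least 2 sites, 30 had at least 2 changed sites, all 30 in a single direction.

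By means over all libraries the largest rise was at chr6:41528449 (hg19), from 6.16% ± 11.8 (SD, 310 controls) to 30.8% ± 28.9 (SD, 75% of patients). This was a difference of 24.6 points (SE 1.68, limma adjusted p = 7.1e-44), or 5.0-fold. Over all libraries, including those with fewer than 20 reads there, the median number of reads at this site was 88 in patients and 0 in controls, of whom 64.1% had no read. The level at chr17:80358809 rose from 17.1% ± 20.8 (SD, n = 240) to 41.3% ± 28.3 (SD, 80.2% of patients). The order of these 2 differed between settings. The rise at chr17:80358809 was the larger by medians (29.8 against 20.1 points) and among libraries matched on total reads (21.3 against 17.7 points). It was the smaller with both sets read (12.3 against 23.4 points) and with the library profile as a factor (16.6 against 24.3 points). Among patients the level at chr17:80358809 was 30.6% with both sets read and 53.4% without set A. At that site 75.3% of controls had no read. Sites read in most libraries of both groups rose as well. At chr21:36421467, the deepest of the named sites, the level rose from 10.7% ± 8.18 (SD, 99.8% of controls) to 29.4% ± 20.9 (SD, n = 1221), a difference of 18.7 points (SE 0.713, limma adjusted p = 1.1e-129). At chr6:31527889 it rose from 7.85% ± 9.01 (SD, 86.7% of controls) to 28% ± 25.3 (SD, 89.3% of patients). The sites chr2:113931518 and chr19:36233435 rose by 20.6 and 20.01 points, with SE of 0.938 and 0.925. The other named higher sites were chr17:55456535, chr16:29757318, chr10:101606024 and chr5:171538557, with differences of 19.1, 18.7, 16.6 and 15.5 points. In relative terms, the steepest of these last 4 was chr5:171538557, at 4.26-fold (4.75% to 20.2%).

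By means over all libraries the largest fall was at chr10:88684020, from 77% ± 12 (SD, 94.7% of controls) to 59.2% ± 14.8 (SD, 80.9% of patients). The difference was -17.8 points (SE 0.619, limma adjusted p = 1.7e-148), with median depths of 75 and 81 reads at the site over all controls and patients. The next was chr4:38673144, which fell from 82% ± 10.1 (SD, 34.8% of controls) to 68.8% ± 17.1 (SD, 76% of patients). Methylation at chr6:170494251 fell from 93% ± 7.11 (SD, n = 330) to 81.3% ± 15.4 (SD, 88.2% of patients), and at chr7:27155000 from 92.9% ± 8.43 (SD, 52.3% of controls) to 81.8% ± 17.3 (SD, 66.7% of patients). The sites chr1:158259914, chr13:112612344, chr13:112602462, chr10:126827002, chr13:106834942 and chr3:194826585 had differences of -12.5, -12, -11.6, -11.3, -10.7 and -10.4 points. The fall at chr10:88684020 was not the largest without set A, where chr6:170494251 fell by 18.3 points, nor with read-share components. Nor was it among samples with values at 80% of the sites, where it was 13.4 points against 14.9 at chr1:158259914 and 13.7 at chr4:38673144. At chr13:112602462, with a level in 13.2% of controls, the difference was -7.0 points at a coverage minimum of 10 reads and -6.13 points over all reads, and the adjusted p was lost at a minimum of 50 reads (0.26, difference -11.6). With read-share components as covariates, the difference was smaller at all 20 named sites, higher ones included, by a median of 1.55 times (1.21 to 3.23) and by over 1.5 times at 15 of them. It was -7.76 points (SE 0.839) at chr10:88684020, 13.7 points (SE 2.80) at chr6:41528449 and 12.1 points (SE 1.26) at chr21:36421467. In this setting chr13:112612344 lost its adjusted p (0.15, difference -7.08, SE 4.19, against SE 2.07 before) and chr13:106834942 fell under the size threshold (-3.33 points, SE 1.42).

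**Figure D2:**
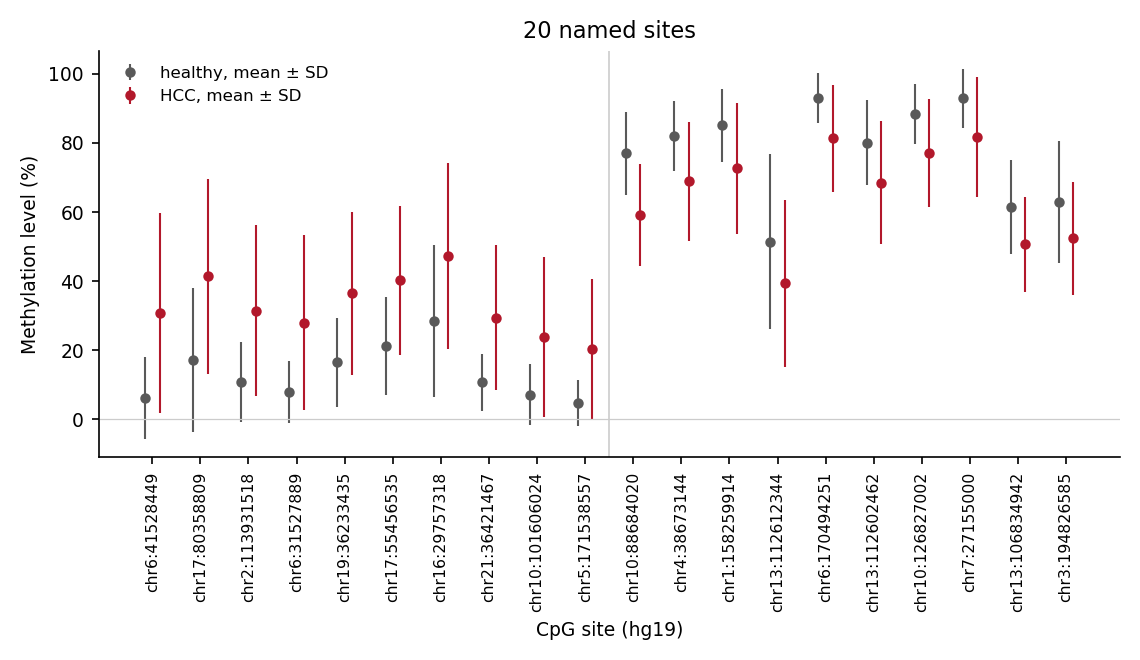
Methylation level (y axis, percent) at the 20 named sites (x axis, hg19 positions) in healthy controls and HCC patients, with points for means and bars for 1 SD over samples. The 10 higher sites stand on the left and the 10 lower sites on the right, and the bars of both groups overlap at each site.

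Which sites had reads differed between the groups. Both sets were read in 33% of the libraries of patients and 91.8% of those of controls. Set A was without reads in 36.9% of the libraries of patients and 8.25% of those of controls. Set B was without reads in 30.1% of the libraries of patients and in 0 of those of controls, so no comparison was possible within that profile. Differences within the first 2 profiles correlated with r = 0.871 (Spearman's rho = 0.831) across the sites tested in both, 71.5% of all, and sites are not independent replicates. Of the sites changed where both sets were read, 99.3% were also changed over all libraries, in the same direction. Libraries with both sets read are part of all libraries and held 91.8% of the controls, so this overlap is partly built in. In both profiles 79 sites were changed in the same direction and 2 in opposite directions. The difference depended on the profile at 32% of the sites tested in both profiles (limma interaction, adjusted p under 0.05).

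**Figure D3:**
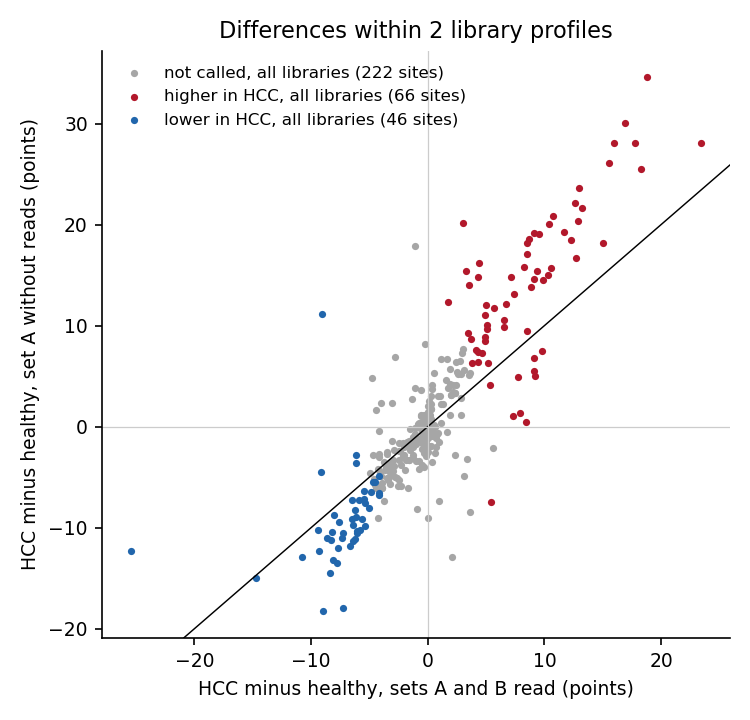
Difference of mean methylation, HCC minus healthy, in percentage points within libraries in which both site sets were read (x axis) and within libraries without reads at set A (y axis). Each point is 1 site, coloured by its call over all libraries, and the line marks equal differences. Most higher sites lie above the line, and r across sites was 0.871.

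All named sites that could be tested kept their direction within both profiles. Where both sets were read, the rise was 23.4 points (SE 1.82) at chr6:41528449, 12.3 points (SE 2.04) at chr17:80358809 and 15.5 points (SE 0.805) at chr21:36421467. In the profile without set A, the rise was 28.1 points (SE 5.22) at chr6:41528449 and 26.1 points (SE 2.38) at chr21:36421467. The difference at chr10:88684020 was -25.4 points (SE 0.684) where both sets were read and -12.3 points (SE 2.62) without set A. Of the 20 named sites, 13 had enough samples for the second profile.

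Patients differed more from each other than controls did. The SD was at least 1.5 times as large in patients at 34.9% of the sites and correspondingly smaller at 6 sites (limma on absolute deviations). Of the 92 higher sites 52 were more variable, of the 73 lower sites 45, and of the sites not called 66 (21.9%). The median SD ratio was 1.58, 1.70 and 1.18 in these groups of sites. At chr21:36421467 the ratio was 2.56 and at chr5:171538557 it was 3.03. The call rested on the percent scale. On the logit scale 6 sites were more variable in patients and 9 were less variable. Within libraries in which both sets were read, 27.4% of the sites were more and 34 sites less variable.

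Over all libraries, a minority of patients lay outside the range of controls at any named site. The median over the 20 sites was 26.9% of patients beyond the limit of the central 95% of controls. At chr21:36421467 this was 467 of 1221 patients (38.2%, exact 95% interval 35.5% to 41%), above 31.2% methylation. At chr6:31527889 it was 36.5% of patients, and at chr5:171538557 it was 35.1%. Below the limit of 50.8% at chr10:88684020 lay 30.3% of patients (exact 95% interval 27.4% to 33.2%). Among patients with both site sets read, 50.7% lay below the limit taken from controls with both sets read. The limit at chr13:112612344 was 0%, so that no sample could lie below it. Beyond the most extreme control lay a median of 6.50% of patients.

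Single sites separated the groups in part. Of the 467 sites, 1 had an AUC of at least 0.8 and 1 an AUC of at most 0.2. These were chr21:36421467 at 0.801 (95% interval 0.782 to 0.818) and chr10:88684020 at 0.178 (0.159 to 0.198), where an AUC under 0.5 means lower levels in patients. At thresholds of 0.7 and 0.3 there were 39 and 28 sites. Where both sets were read, the AUC was 0.754 at chr21:36421467 and 0.0639 at chr10:88684020, the 1 site left beyond 0.8 or 0.2.

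All sites together gave a AUC of 0.957 in cross-validation (95% interval 0.949 to 0.964), with a median of 177.5 sites kept per fold. Which values were missing, without any methylation level, gave 0.9905 (95% interval 0.987 to 0.994). Which sites had no read gave 0.981 over all libraries, 0.9796 where both sets were read and 0.961 in the profile without set A. The methylation classifier had an AUC of 0.981 within libraries with both sets read. Trained there and tested on the 450 patients and 80 controls without set A, it had an AUC of 0.797 (0.753 to 0.842).

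**Figure D4:**
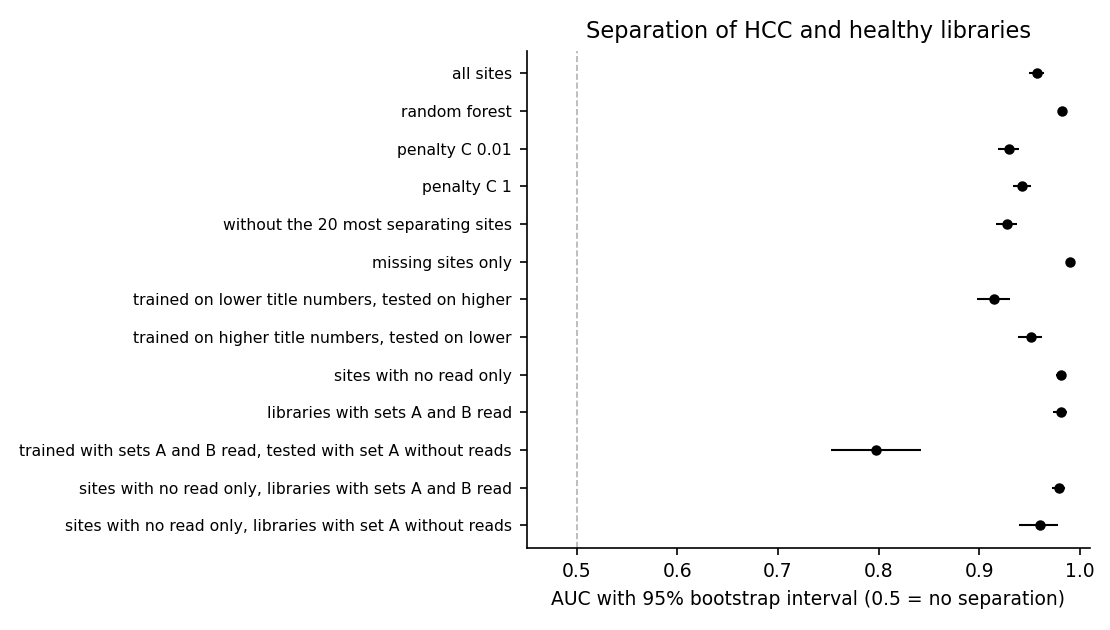
AUC for telling HCC from healthy libraries (x axis, 0.5 is no separation) for each classifier (y axis), with bars for 95% bootstrap intervals. The value for missing sites alone, 0.9905, lies above that for methylation levels at all sites, 0.957, and the transfer between profiles is lowest at 0.797.

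Levels at neighbouring sites went together, more so in patients. Over pairs of sites within 200 bases the median Pearson r between sites across samples was 0.647 in patients (250 pairs, quartiles 0.494 and 0.764) and 0.245 in controls (quartiles 0.115 and 0.357). Over pairs on different chromosomes it was 0.0456 in patients and 0.0023 in controls. Within libraries with both sets read the medians of neighbouring pairs were 0.658 and 0.252. The median Spearman correlation of neighbouring pairs was 0.466 in patients and 0.220 in controls. No test was made across pairs, and the difference between the groups was not tested. These correlations were not made at equal depth, and the median number of reads per site was 64 in patients and 31 in controls. Depth and the wider spread among patients are therefore not separated from the group here. Whether neighbouring sites were read on the same fragments was not examined.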

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

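The tests of library profiles, read depth and DNA sources in this part were chosen after the results had been seen, while the comparison with other splits of the samples was planned. At 8 named sites the difference between patients and controls was not the same in the 2 library profiles (limma interaction, adjusted p under 0.05). The values are the difference without set A minus the difference with both sets read. The rise was larger in libraries without set A by 10.4 points at chr2:113931518, 12.1 points at chr6:31527889, 13.1 points at chr19:36233435, 15.8 points at chr16:29757318, 10.6 points at chr21:36421467 and 10.6 points at chr10:101606024. The fall at chr6:170494251 was also larger there (-9.26 points), and the fall at chr10:88684020 was smaller (13.1 points).

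The 92 higher and 73 lower sites stood far from chance, since 1 of 100 splits of the samples, the real one, gave as many, and the highest other split gave 1 changed site. Within libraries with both sets read, where the profile is the same, 82.4% of the changed sites also changed in the same direction. This argues against library profile as the whole cause, though the overlap is partly built in, since these libraries held 91.8% of controls. The profile without set B held no controls, so it could not be compared. With read-share components as covariates, 82 sites were changed. Read depth as the whole cause is argued against by 58.8% of the changed sites changing in the same direction among libraries matched on total reads. The other changed sites fell short there, with differences in the same direction at all of them, so a part that goes with depth stays open. Preparation that differed between the groups in other ways stays open. Which sites had no read separated patients from controls with an AUC of 0.9796 even within libraries with both sets read. Such preparation and the disease can therefore not be told apart here, and both stay open. The labels gave no other property of the samples, such as age or sex, so any other difference between the groups stays open too.

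The site chr10:88684020 separated the groups best, yet did not follow the other changed sites. Its difference was at least 4.70 SE from 0 within both profiles that held controls, which argues against the profile as the whole cause there, and no comparison was possible in the profile without set B. The level still moved strongly with the profile, as it was higher without set A than with both sets read by 23.5 points (SE 1.04) among patients and by 10.4 points (SE 1.93) among controls. If its fall came from the same varying share of 1 DNA source as the other changed sites, it would fall as they move, but its r with their score among patients was 0.040 (rho = 0.061, permutation p = 0.21 and 0.055, adjusted over 4 relations 0.42 and 0.11, r = 0.043 without 2 samples), and within the 3 profiles of patients r was -0.105, 0.034 and -0.0007 (rho = -0.106, -0.0083 and 0.065, lowest adjusted p 0.14 and 0.11). These r values restate that the site did not follow the others, and are not a separate test of a shared source. A batch within the profiles cannot be told apart from the group, since which sites had no read separated the groups with both sets read (AUC 0.9796), and with read-share components as covariates the difference was -7.76 points (SE 0.839) against -17.8 (SE 0.619). A change in HCC that other sites do not share was not tested.

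Raised and lowered sites moved against each other among patients. The mean change of the 92 higher sites and that of the 73 lower sites, both relative to the mean of controls, had r = -0.873 with both sets read, where incomplete bisulfite conversion would move both upward. The weakest r within a profile was -0.733, so the profiles alone do not give it. As a hypothesis, a DNA source whose share varies between patients may move all sites toward its own levels. At the sites on even-numbered chromosomes that were not called, 28.3% of all, the slope on a score from odd-numbered chromosomes went with the difference between the groups (r = 0.871 across sites, which are not independent). Depth or preparation that varies between patients and goes with the group could give the same slopes, so this result does not tell a DNA source from them. The score rose with log2 total reads among patients (r = 0.507 with both sets read, 0.273 without set A and 0.416 without set B). Tumour, liver and blood cells were not told apart as that source.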

How the results depend on the processing

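The alternatives on library profiles, thinned reads, matched total reads, read-share components, quasi-binomial regression, deposited beta values and absent reads were chosen after seeing the data, and the others were planned. Changed sites, 35.3% of all, numbered between 29.3% and 38.3% of all on the logit scale, by rank test, with robust priors, at coverage minimums of 10 and 50, in samples with values at 80% of sites (54.2% of patients, 15.7% of controls), with the mean level as covariate, with thinned reads, by quasi-binomial regression, with the profile as a factor and within both profiles, where the 29.3% without set A were 41% of the sites tested there. With the title number as a replicate block they were 33.8%. On the logit scale, by rank test and with robust priors the size threshold used the same differences of means, so only the adjusted p could change a call. Same-numbered samples did not deviate together over 970 numbers (median correlation -0.0053, 220 pairs over 0.1), and the replicate block changed no call at a named site.

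Sites with values in 80% of each group, 33.2% of all, held changed sites amounting to 11.1% of all (7.07% higher, 4.07% lower, 27.2% at any size), as fewer sites were tested. The difference of medians gave 23.1% (9.64% lower). A size threshold of 2 points gave 62.5% (33.6% lower) and one of 10 points 11.6% (8.57% higher, 2.998% lower). With read-share components as covariates it was 17.6% (10.7% higher, 6.85% lower, 47.1% at any size), and the difference was smaller at all 20 named sites, by a median of 1.55 times. Among libraries matched on total reads it was 21.2% (12.4% higher, 8.78% lower). Without set A (450 patients, 80 controls, 71.5% of sites tested), 42.4% of all sites passed at any size. The deposited beta values gave 35.3% higher sites, against 92 sites, and reversed chr13:112602462 (2.15 points) and chr7:27155000 (5.96 points). In them absent reads count as 0 and values from fewer than 20 reads are kept. More variable sites made up 1.28% on the logit scale, against 34.9%. They were 14.1% of all sites with the 80% filter, where 33.2% of all sites were tested. Without set A they were 19.7% of all sites, with 71.5% of all sites tested. As fewer sites were tested in both settings, these shares of all sites cannot be set directly against 34.9%. As a share of the sites tested, they were above 34.9% with the 80% filter and below it without set A. The smaller number of tested sites alone therefore does not account for the drop without set A, where 80 controls were left. Sites with a separating AUC numbered 67 at 0.7 or 0.3, 0 at 0.9 or 0.1, and 1 with both sets read, against 2. A median of 6.50% of patients lay beyond the extremes of controls.

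In cross-validation the AUC was 0.982 by random forest, 0.930 at C = 0.01, 0.943 at C = 1, 0.928 without the 20 most separating sites, 0.9905 from missing values, 0.915 trained on lower and tested on higher title numbers (0.951 the other way round), 0.981 from absent reads, 0.9796 from absent reads with both sets read, 0.981 from levels with both sets read and 0.797 across profiles. Except where stated, the cause was not tested. The filter on sites of low variance removed none and says nothing. Of the values at named sites under the other alternatives, 97.9% kept their direction and side of the threshold, 5 fell short of it and 2 reversed. This share is partly fixed in advance. On the logit scale, by rank test and with robust priors the direction and size could not change. The difference of medians used the adjusted p of the main test. The alternatives on panels, gene lists and site context were not run, for want of an hg19 annotation. Depth limits the controls most, with a level at a median of 60.6% of the sites.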

Other observations

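The tests in this part were chosen after the data had been seen. The common movement of raised and lowered sites was present in each profile of patients. Among patients r was -0.873 with both sets read (33% of patients, rho = -0.851), -0.834 without set A (n = 450, rho = -0.860) and -0.733 without set B (30.1% of patients, rho = -0.854). The pooled value was -0.810 (n = 1221, rho = -0.856). Among controls it was -0.423 with both sets read (n = 890, rho = -0.334), and -0.249 without set A (n = 80, rho = -0.122), where it fell to -0.106 without the 2 samples farthest from the median. With the same 2-sample omission, r among patients was -0.865, -0.836 and -0.735 within the 3 profiles and -0.811 pooled. In controls with both sets read it was -0.399. Over 7 relations, permutation p was 1e-05, the smallest these permutations give (adjusted 1.2e-05), for both coefficients, except in controls without set A (0.026 for r, adjusted 0.026, and 0.28 for rho, adjusted 0.28). The pooled r in controls was -0.431 (rho = -0.351, -0.410 without 2 samples).

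The slopes of sites on even-numbered chromosomes on the odd-chromosome score went with the group difference in controls as well, with r = 0.773 across 45.2% of all sites, against 0.924 in patients. At those of them not called, r was 0.502 in controls. Of the changed sites, 88.5% correlated with the score of the other chromosomes by more than 0.3 in the direction of their change among patients, and 7 sites, chr10:88684020 among them, by less than 0.1. Another 2 of those 7 are named here after their values had been seen. At chr6:16729606 the difference was -9.06 points (SE 0.767) with both sets read and 11.2 points (SE 2.44) without set A. At chr17:75539901 it was 5.39 points (SE 0.907) and -7.48 points (SE 1.90). These were the 2 sites called in opposite directions in the profiles, and it was mainly the level of controls that moved with the profile. Without set A minus both sets read, it moved by -27.2 points (SE 1.58) at chr6:16729606 and 17.4 points (SE 1.81) at chr17:75539901 among controls, against -6.94 points (SE 1.16) and 4.56 points (SE 1.02) among patients. Among controls, 47 of the sites tested in both profiles, which were 71.5% of all, were changed between the profiles. Among patients 26 were, of the 440 sites with at least 20 patients in each of these profiles.

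The score of raised minus lowered sites was higher in deeper libraries of patients and not detectably so in controls. Its r with log2 total reads was 0.507 with both sets read (rho = 0.390), 0.273 without set A (rho = 0.250) and 0.416 without set B (rho = 0.385). Without the 2 samples farthest from the median depth these were 0.487, 0.271 and 0.408, and permutation p was 1e-05, the smallest possible (adjusted 1.7e-05 over 5 relations). Among controls r was -0.028 (rho = -0.032, p = 0.4 and 0.34, adjusted 0.4 and 0.34) with both sets read and -0.146 (rho = -0.130, p = 0.2 and 0.25, adjusted 0.25 and 0.31) without set A. Leaving out 2 samples gave -0.034 and -0.157. Total reads alone separated patients from controls with an AUC of 0.813 (95% interval 0.796 to 0.830).

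A plain score carried over between profiles where the penalised classifier lost. Sites changed within libraries with both sets read were averaged as raised minus lowered. On the 450 patients and 80 controls without set A, this score had an AUC of 0.947 (95% interval 0.922 to 0.969), against 0.797 for the classifier trained on the same libraries. The difference between these AUCs was not tested. In the libraries without set A, which sites had no read gave an AUC of 0.961 in cross-validation. The score of all raised minus lowered sites rose with log2 total reads among patients there (r = 0.273). The AUC of 0.947 therefore does not tell the disease from preparation or depth that goes with the group.

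The deposited beta values list 0 where a site had no read and keep values from fewer than 20 reads. With them, 49.7% of the sites counted as changed, 35.3% higher and 67 sites lower. In all, 22.9% of the sites were also changed in the same direction by levels from at least 20 reads, 27 sites were changed in the opposite direction and 98 were changed by the deposited values alone. Differences by the 2 ways correlated with r = 0.321 across sites. The largest deposited difference was at chr4:1324870, -53.7 points, where levels from reads differed by 0.493 points (SE 0.375, limma adjusted p = 0.22). At that site 65.4% of patients and 8.14% of controls had no read.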
